A study of Gallus gallus with 6 samples.

How the data were processed

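Messenger RNA was sequenced from lens fiber cells of chick embryos at embryonic day 13. Per the labels' protocols, whole lenses were kept in organ culture, each pool held 10 to 15 lenses, the fiber cells were separated from the epithelium by microdissection, and libraries came from the TruSeq stranded mRNA kit. There were 3 pools of untreated lenses taken at 0 h and 3 pools taken after 8 h in 1% O2, and the labels call the pools of a group biological triplicates. The series also holds a chromatin part and cultures in normal oxygen, which are not analysed here. The RNA-seq libraries analysed here include 0 that were held 8 h in normal oxygen, so oxygen and time in culture change together in every comparison.

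The deposited table gives, for each of 9107 gene rows, a score per library, and these scores are read counts that the authors had divided by a size factor per library and rounded to whole numbers. That unit was worked out from the values. The median ratio of each library to the gene-wise geometric mean lay between 0.992 and 1.016, as it does after median-ratio scaling. Among the lower values of the untreated columns, regular steps of whole numbers never occurred. The authors also deposited a shrunken log2 fold change and an adjusted p-value for 8 h over 0 h, per the file headers. Per the submitters' processing notes the genome build was galGal6 and the tools named were STAR, DESeq2, cutadapt, Bowtie2, HISAT2, StringTie and edgeR, without versions or roles. The counting program, the annotation and whether counting used the strand are not given in the sources used here. Reads of near-identical genes, such as the delta-crystallin pair ASL1 and ASL2, can therefore have been split between copies, and the values of overlapping or antisense genes carry the same uncertainty.

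The table named genes by symbol only. It held 9095 distinct symbols, 12 of them on 2 rows, which were kept as separate rows, and 8668 rows had a symbol found in a RefSeq gene table of assembly GRCg7b. Because that assembly is not the submitters' build, no coordinates are given. On 6 rows the symbol was a bare number, and these rows were never named. The row of METTL16 was left out because 1 of its values, 0.61, was not whole and equalled the authors' log2 fold change of that row. Few low rows were present (48 with a mean under 20), so genes of low expression were largely outside what was tested, and gene list members with no row are not analysed here. The number of columns with values of unknown samples was 0.

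The size factor of each library was recovered from the steps in its rounded values: a factor under 1 leaves whole numbers that cannot occur, and a factor over 1 makes some occur more often. The factors were 0.849, 0.937 and 0.744 for untreated pools 1 to 3 and 1.16, 1.27 and 1.09 for hypoxia pools 1 to 3. The search used only the lower values of each library. Among those, no value of the untreated libraries lay at a whole number that its factor rules out (0 rows in each library). The factors were chosen to match these same values. On simulated rounded values the search missed the true factor by at most 0.0006%. Multiplying the values by these factors gives the reads behind the table: 24.7 M, 29.1 M and 23.5 M for the untreated pools and 30.6 M, 32.6 M and 29.4 M for the hypoxia pools. Intervals from such reads cover counting error only.

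The analysis fixed before the data were examined foresaw a count model for counts and limma for normalized values, and the latter applied because the table does not hold counts. The edgeR test named there for counts was therefore not run, and DESeq2 was not run either. Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, with the group as the only term, a mean-variance trend and robust empirical Bayes moderation, on the 9105 rows with a mean of at least 1. Adjusted p-values are Benjamini-Hochberg values from that fit, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Where a group was listed at 0 in all libraries no fold is given. Where a group had 1 to 3 recovered reads, the ratio of reads is given with its exact 95% interval, corrected for the summed size factors of each group. In simulated data for the same 9105 genes with 200 changed ones, the fit recovered 88% of genes changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, and 7 of 198 calls were of unchanged genes. The simulated changes were equally often up and down, spared the lowest genes and had a known scaling. The real fit called 5017 genes and its scaling is uncertain, so the simulation does not give the error rate of the real calls.

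There were 22 gene lists fixed before the data were examined, 6 of them primary, 11 secondary and 5 of markers of other cell types. They were matched on the symbol column. Each list has its count of called members over all genes tested and adjusted over the list alone, a camera test with a preset correlation of 0.01, camera with an estimated correlation, and fry, with Benjamini-Hochberg adjustment over the 22 lists. The genes named were set by rule: the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 and groups that did not overlap, the 4 members with the smallest p of each primary list and the 2 of each other list, the 5 genes with the highest mean level, and HIF1A, BNIP3L, SLC2A1 and KDM3A. Genes named outside the rule are marked as chosen after their values were seen. Some genes that the rule names are not reported.

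Before averaging, libraries of a group were compared for duplicates with a chi-square per gene on recovered reads, which was 8.59 to 48.3 and so well above the sampling noise of about 1. Alternatives were library totals as the scaling, the trimmed mean of M-values computed on recovered reads, recomputed median-ratio factors, scaling without the crystallins, other filters (none, or a mean of at least 5), pseudocounts of 0.1 and 5, the replicate number as a block, each library left out in turn, a test against a 1.5-fold change, an adjusted p under 0.01 and a fold change of at least 2. After seeing the data, limma's voom on recovered reads and list counts without untreated pool 1 were added. Random lists for comparison were 10000 draws matched on mean level, each member replaced by 1 of its 50 nearest genes by rank. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.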

Results

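RNA-seq measured transcript levels in lens fiber cells, the elongated cells that make up the bulk of the lens, dissected from chick lenses at embryonic day 13. The question set by the series was which genes change over 8 h of hypoxia. Untreated pools at 0 h (n = 3) were compared with pools after 8 h in 1% O2 (n = 3), each of 10 to 15 lenses. The libraries held 23.5 M to 32.6 M reads on the genes of the deposited table, with means of 25.8 M in the untreated and 30.9 M in the hypoxia group. A single gene, ASL1, which encodes delta-crystallin, the main lens protein of birds, took 48.2% to 53.1% of each library, and the 10 highest genes together took 59.1% to 64.4%. Levels are normalized counts, mean ± SD over the 3 pools of a group, and log2 fold changes are 8 h over untreated, ± SE.

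Of 9105 genes tested, 2681 were higher and 2336 lower after 8 h in 1% O2 (limma, adjusted p under 0.05). Among these, 926 rose and 361 fell at least 2-fold, and 106 rose and 32 fell at least 8-fold. In 5712 genes (62.7%) the 3 values of 1 group all lay above the 3 of the other, where chance gives 10%. The rises were larger than the falls at the extremes, which the plot of fold change against mean level shows. No library kept 8 h in normal oxygen was analysed here, so the differences are those of 8 h in culture at 1% O2, not of oxygen alone. Scaling by library totals moved the median of all genes by 0.216 on the log2 scale and the calls to 3647 higher and 976 lower, or 78.9% higher against 53.4%. The trimmed mean of M-values and scaling without the crystallins moved that median by 0.001 and 0.013. ASL1 alone took 48.2% to 53.1% of each library, so a change in it shifts every gene when library totals are the scaling.

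**Figure D1:**
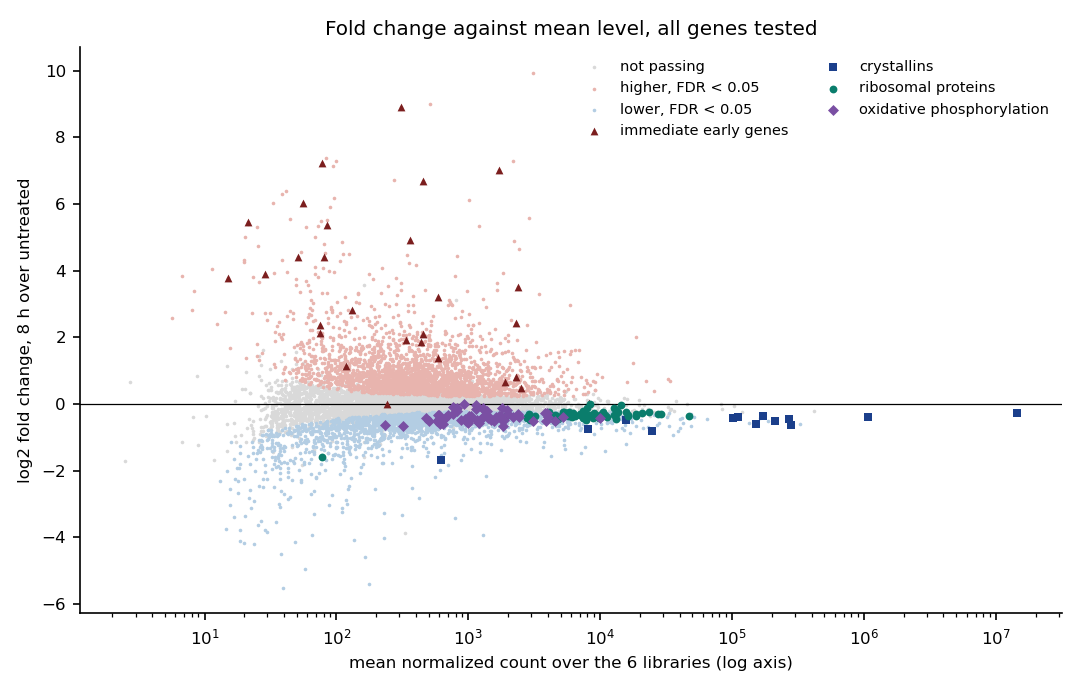
Log2 fold change of 8 h in 1% O2 over untreated (vertical) against the mean normalized count of the 6 libraries (horizontal, log axis), 1 point per gene for the 9105 genes tested, pale red and pale blue for genes called higher and lower. Dark symbols mark 4 gene lists: immediate early genes have a median of 3.01, and crystallins, ribosomal proteins and oxidative phosphorylation genes have medians of -0.50, -0.34 and -0.41.

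The largest rises belonged to genes nearly silent in untreated lenses. CHAC1, a glutathione-degrading enzyme gene switched on by the ATF4 stress pathway, went from 5.7 ± 2.9 to 6232 ± 1144 (log2 fold change 9.94 ± 0.27), and SESN2, a stress-induced inhibitor of mTORC1 signalling, from 27.0 ± 4.6 to 4363 ± 557 (7.29 ± 0.14). HBEGF, a ligand of the EGF receptor, stood at 7, 0 and 0 in the untreated libraries and at 1026 ± 112 after 8 h (9.0 ± 0.80). Without untreated pool 1 the untreated group is listed at 0, so no fold is given, and HBEGF was still called higher (adjusted p = 4.08e-09, 4.08e-09 to 0.00258 over its alternatives). The transcription factor gene EGR2 had 1 read in all untreated libraries and 2170 after 8 h. Corrected for size factors its ratio was 1560, with an exact 95% interval of 279 to 61600. PIK3R5, a regulatory subunit of PI3-kinase, had 1 and 695 reads, a corrected ratio of 499 (89.3 to 19700). KCNF1, a potassium channel subunit, was listed at 0 in all untreated libraries and stood at 166 ± 22 after 8 h. Adjusted p-values of these 6 genes ran from 5.45e-11 for SESN2 to 0.000137 for HBEGF.

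Among the largest falls, NRIP3 went from 319 ± 28 to 12.7 ± 4.0 (-4.59 ± 0.25), CYP26A1, which breaks down retinoic acid, from 73.7 ± 6.7 to 2.7 ± 2.1 (-4.50 ± 0.49), and RRM2, a ribonucleotide reductase subunit needed for DNA synthesis, from 46.0 ± 27.4 to 1.3 ± 0.6 (-4.20 ± 0.59). The Wnt inhibitor gene DKK1 stood at 191, 15 and 30 in the untreated libraries and was listed at 0 in all hypoxia libraries. COL9A1, a collagen IX chain, went from 112 ± 66 to 3.7 ± 4.0 (-4.95 ± 0.76), and R3HDML from 345 ± 313 to 5.7 ± 3.1 (-5.39 ± 0.65). Their untreated or hypoxia values were uneven: without hypoxia pool 1 the COL9A1 log2 fold change was -4.09 and without hypoxia pool 2 it was -5.67, while R3HDML gave -4.68 without untreated pool 1 and -5.98 without untreated pool 2. With voom the call of R3HDML was lost (adjusted p = 0.0784, with 3.91e-05 to 0.0784 over its alternatives), and for DKK1 and COL9A1 the authors' deposited table lists no adjusted p.

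Of 22 genes measured for glucose uptake, glycolysis and lactate export, 12 were higher, 3 lower and 7 did not pass (12 and 4 adjusted over the list alone). HK2, which traps glucose in the cell as its phosphate, rose from 271 ± 56 to 1750.0 ± 97.4 (2.71 ± 0.15), and PFKFB3 and PFKFB4, which make the activator of phosphofructokinase, rose by 2.24 ± 0.09 and 2.07 ± 0.12 on the log2 scale. ENO2, an enolase, rose from 388 ± 5 to 1691 ± 209, and SLC2A1, the glucose transporter GLUT1, from 12284 ± 1178 to 19546 ± 1966 (0.67 ± 0.11). The 3 lower members, named after their values were seen, were the enolase gene ENO1 (-0.57 ± 0.18), PFKL (-0.31 ± 0.10) and HK1 (-0.22 ± 0.09), and none of these was lower when libraries were scaled by their totals. Without hypoxia pool 2, 1 member of the list was lower. The list stood above other genes by camera (adjusted p = 0.0286), with adjusted p = 0.717 with an estimated correlation and adjusted p = 0.0628 without hypoxia pool 1 (0.00315 to 0.717 over its alternatives).

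Targets of the hypoxia-inducible factors (HIF) and oxygen-sensing genes rose in most cases. Of 28 measured, 20 were higher, 4 lower and 4 did not pass, with the same counts adjusted over the list alone. STC2, a secreted glycoprotein hormone, rose from 228 ± 27 to 3464 ± 214 (3.93 ± 0.11), and VEGFA, the vascular growth factor, from 165 ± 18 to 1322 ± 52 (3.00 ± 0.11). EGLN3, a prolyl hydroxylase that marks HIF for destruction, rose from 120 ± 11 to 600.0 ± 69.2 (2.31 ± 0.13), and the circadian repressor gene BHLHE40 by 2.36 ± 0.15 on the log2 scale. HIF1A itself, the oxygen-regulated HIF subunit, fell from 6071 ± 1068 to 3516 ± 362 (-0.78 ± 0.13, adjusted p = 0.000628). The other lower members, named after their values were seen, were NDRG1 (-0.79 ± 0.13), PLOD1 (-0.71 ± 0.12) and FAM162A (-0.66 ± 0.11). As a list these genes rose by camera (adjusted p = 0.000871), with adjusted p = 0.327 with an estimated correlation.

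Mitophagy and autophagy genes moved both ways. Of 37 measured, 12 were higher, 8 lower and 17 did not pass (11 and 8 adjusted over the list alone), the median log2 fold change was 0.02, and camera called no shift (adjusted p = 0.834). BNIP3L, a receptor that marks mitochondria for removal in lens fiber cells and red cells, was at 14728 ± 766 before and 14784 ± 450 after (0.01 ± 0.09, 95% interval -0.19 to 0.20, adjusted p = 0.958). That interval holds for the deposited scaling only, as library totals moved the median of all genes by 0.216. BNIP3L did not pass under any alternative (adjusted p 0.055 to 0.97). TFEB, a master regulator of lysosome genes, rose from 407 ± 38 to 1038 ± 80 (1.35 ± 0.11). UVRAG rose by 1.22 ± 0.19 on the log2 scale, and the kinase gene ULK2 and its partner RB1CC1, both of the complex that starts autophagy, by 0.69 ± 0.11 and 0.58 ± 0.11. Without untreated pool 1, 7 members were higher and 8 lower, and with library totals 16 were higher and 1 lower.

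Of 13 crystallin genes measured, 11 were lower, 0 higher and 2 did not pass (13 lower and 0 higher adjusted over the list alone), with a median log2 fold change of -0.50 and adjusted p = 0.000591 by camera, but adjusted p = 0.661 with an estimated correlation. CRYGS fell most, from 948 ± 67 to 293 ± 24 (-1.69 ± 0.11). CRYBA4 fell from 31294 ± 2695 to 17899 ± 1287 (-0.81 ± 0.10), the galectin-related lens protein gene GRIFIN by 0.75 ± 0.11 on the log2 scale, and CRYAB, a small heat shock protein, from 337556 ± 4458 to 219567 ± 29659 (-0.63 ± 0.12). CRYAA was at 1208930 ± 48825 and then 921315 ± 169134 (-0.41 ± 0.14, adjusted p = 0.0256, 0.0039 to 0.282 over its alternatives). Its call ended without untreated pool 1, 2 or 3, where the log2 fold change stayed at -0.40, -0.38 and -0.44, and without hypoxia pool 3 (-0.27) and with library totals (-0.19). ASL1 had a log2 fold change of -0.28 ± 0.12 (adjusted p = 0.0632), which did not pass, although the authors' deposited table gives an adjusted p of 0.0166. It passed without hypoxia pool 3 (-0.33), with recomputed median-ratio factors (-0.29) and with the replicate block (adjusted p = 0.0178). Over its alternatives the adjusted p of ASL1 ran from 0.0178 to 0.604. ASL1 and ASL2 are near-identical and their reads can have been shared. With library totals 6 crystallins were lower and the list's median was -0.28. Because ASL1 alone took 48.2% to 53.1% of each library total, that scaling by itself takes out part of a crystallin fall.

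Other lens fiber genes divided, with 13 of 32 higher, 9 lower and 10 not passing (14 and 9 adjusted over the list alone), and camera called no shift (median 0.10, adjusted p = 0.477). CDKN1B, the cell cycle inhibitor p27 of differentiating fiber cells, rose from 2657 ± 174 to 7084 ± 643 (1.41 ± 0.10), and the ephrin receptor gene EPHA2 from 1927 ± 100 to 4199 ± 416 (1.12 ± 0.10). The transcription factor genes SOX1 and SOX2 rose by 1.25 ± 0.13 and 1.06 ± 0.12 on the log2 scale. BFSP1, a subunit of the beaded filament cytoskeleton and among the 5 most abundant transcripts, fell from 398023 ± 39639 to 259457 ± 25548 (-0.62 ± 0.12). With library totals 16 members were higher and 5 lower. YBX1, an RNA-binding protein gene also among the most abundant, was at 445859 ± 15168 before and 384581 ± 22044 after (-0.21 ± 0.10, adjusted p = 0.0997), and at a log2 fold change of 0.002 with library totals.

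Genes of enzymes that add or remove histone methyl groups were more often higher than lower: 18 of 41 were higher, 1 lower and 22 did not pass (17 and 0 adjusted over the list alone). KDM2A, a demethylase of histone H3 lysine 36, rose from 417 ± 52 to 1073 ± 134 (1.36 ± 0.12), and DOT1L, the methyltransferase of H3 lysine 79, from 832 ± 114 to 1920 ± 188 (1.21 ± 0.12). SETD2, which adds the trimethyl mark at H3 lysine 36, rose from 952 ± 45 to 1887 ± 192 (0.98 ± 0.10), and KDM5A, a demethylase of H3 lysine 4, from 1305 ± 99 to 2653 ± 365 (1.02 ± 0.11). KDM3A, an H3 lysine 9 demethylase and a HIF target, rose by 0.56 ± 0.12 on the log2 scale. The lower member, named after its values were seen, was KDM1A (-0.27 ± 0.11, adjusted p = 0.0498). The list rose by camera (adjusted p = 0.020), with adjusted p = 0.661 with an estimated correlation and adjusted p = 0.0749 without hypoxia pool 2 (0.00706 to 0.661 over its alternatives).

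**Figure D2:**
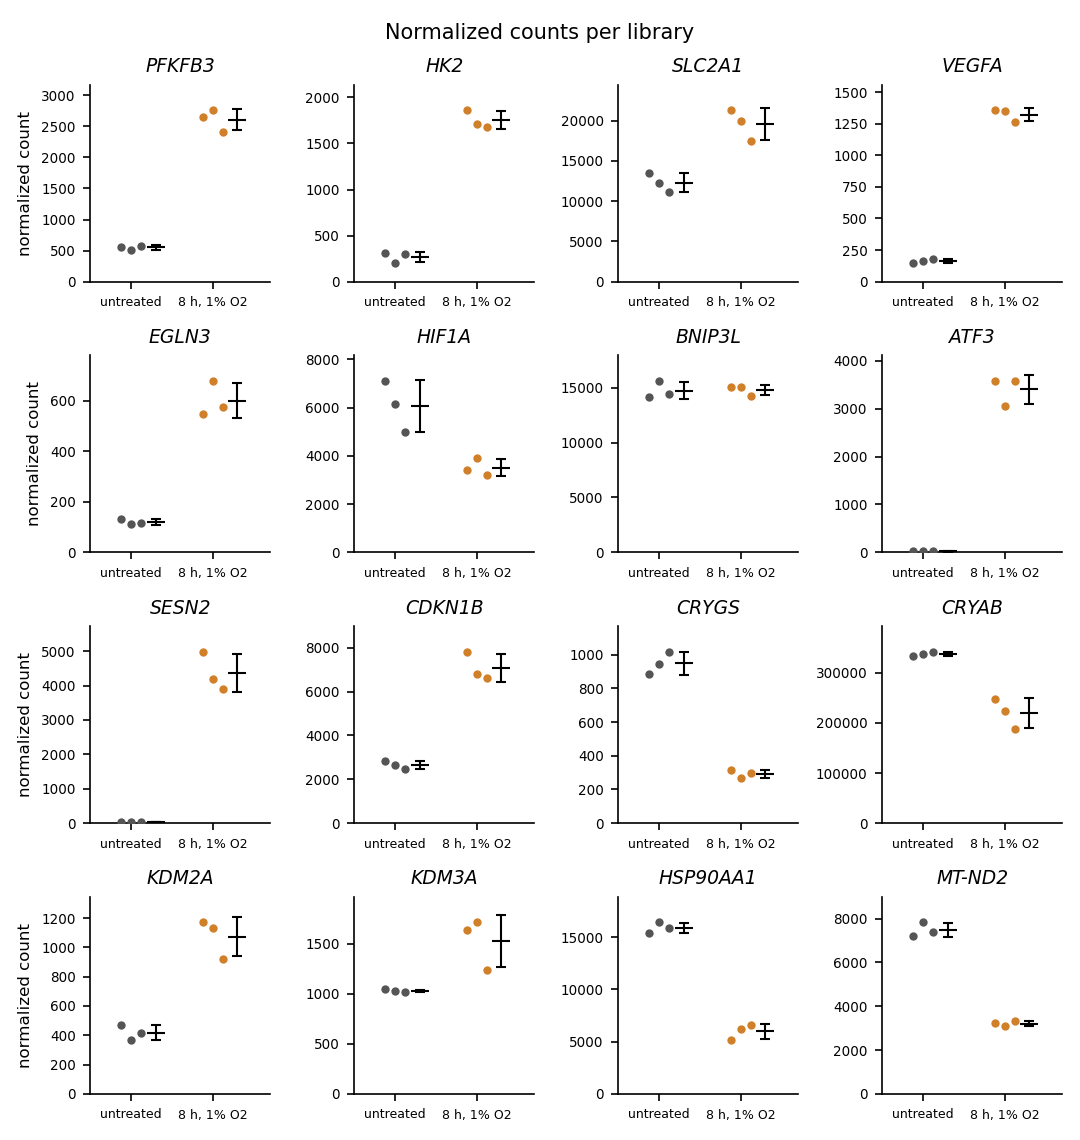
Normalized count of 16 genes (vertical axis of each panel, from 0) in the 3 untreated and 3 hypoxia libraries, 1 point per library, with the mean and SD beside the points. The hypoxia values of HK2 (1750.0 ± 97.4) lie above and those of HIF1A (3516 ± 362) below all untreated values, while those of BNIP3L overlap.

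Immediate early genes, which respond within minutes to growth factors, dissection or stress, were the list that moved furthest. Of 28 measured, 26 were higher and 0 lower, with the same counts adjusted over the list alone and a median log2 fold change of 3.01. EGR3 and FOSB were listed at 0 in untreated libraries. Setting them to a floor of 3 reads per group left the median as it was, which it had to, because both stay above it. ATF3, a stress-induced transcription factor, rose from 25.7 ± 8.1 to 3397 ± 298 (7.03 ± 0.19), and GADD45B from 381 ± 13 to 4361 ± 587 (3.51 ± 0.11). By camera the rise had adjusted p = 4.7e-12, with adjusted p = 0.382 with an estimated correlation.

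Of 34 genes of the unfolded protein and amino acid response, 22 were higher and 6 lower, with the same counts adjusted over the list alone. STC2 and SESN2, both given above, had the smallest p in this list. The rise had adjusted p = 2.72e-05 by camera, with adjusted p = 0.661 with an estimated correlation. The 6 lower members were 3 without untreated pool 3 and 0 with library totals. Of 27 heat shock protein and chaperone genes, 13 were lower, 5 higher and 9 did not pass (14 and 5 adjusted over the list alone, median -0.31). HSP90AA1, the inducible form of HSP90, fell from 15893 ± 492 to 5971 ± 716 (-1.42 ± 0.11), while HSF2, a heat shock transcription factor, rose from 727 ± 19 to 2265 ± 107 (1.64 ± 0.08). The fall of the list had adjusted p = 0.0311 by camera, adjusted p = 0.661 with an estimated correlation, and 0.0668 and 0.0653 without hypoxia pools 1 and 2 (0.00729 to 0.661 over its alternatives). With library totals its median was -0.09, with 11 lower and 7 higher.

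Of 62 nuclear-encoded respiratory chain genes, 49 were lower, 0 higher and 13 did not pass, also adjusted over the list alone, with a median log2 fold change of -0.41. NDUFV2 fell from 1192 ± 64 to 809 ± 53 (-0.56 ± 0.09) and NDUFA4 from 2238 ± 59 to 1434 ± 226 (-0.65 ± 0.11). Of 13 genes of the mitochondrial genome, 9 were lower and 0 higher (10 and 0 adjusted over the list alone, median -0.57), with MT-ND2 falling from 7472 ± 323 to 3207 ± 125 (-1.22 ± 0.09) and ND4L by 1.21 ± 0.12 on the log2 scale. Camera gave adjusted p = 2.06e-10 and 0.000182 for these lists, and adjusted p = 0.661 for both with an estimated correlation. With library totals 22 of the 62 and 6 of the 13 were lower, and the medians were -0.19 and -0.35. Random lists matched on mean level to the genes of the mitochondrial genome had a median of -0.241, so genes of that level were lower too.

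Calls of ribosomal protein genes were largely lost with library totals, while the other scalings left the list's median near its value of -0.34. That median was -0.34 with the trimmed mean of M-values, -0.35 with recomputed median-ratio factors and -0.33 with crystallins left out. Of 64, 51 were lower, 0 higher and 13 did not pass (55 lower and 0 higher adjusted over the list alone, median -0.34), but 1 was lower with library totals, where the median was -0.12. Leaving out untreated pool 1, untreated pool 3 or hypoxia pool 2 left 30, 27 and 28 lower. RPS26 fell from 118 ± 15 to 38.3 ± 6.4 (-1.60 ± 0.22), and RPL3 from 15210 ± 624 to 11105 ± 948 (-0.46 ± 0.10), a call that library totals ended (-0.24, adjusted p = 0.0635, 0.000649 to 0.0635 over its alternatives). Their fall had adjusted p = 1.78e-09 by camera, with adjusted p = 0.717 with an estimated correlation. Of 24 sterol synthesis and uptake genes, 12 were lower and 3 higher (13 and 4 adjusted over the list alone, median -0.28), among them DHCR7 (991 ± 87 to 536 ± 53, -0.89 ± 0.11), which reduces 7-dehydrocholesterol to cholesterol. For this list camera gave adjusted p = 0.0311, adjusted p = 0.717 with an estimated correlation, and 0.057 and 0.0779 without untreated pool 3 and hypoxia pool 2 (0.0148 to 0.717 over its alternatives). With library totals 8 of its genes were lower and 7 higher, with a median of -0.06.

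Of 37 proliferation genes measured, 17 were lower, 7 higher and 13 did not pass, also adjusted over the list alone, with a median log2 fold change of -0.81. RRM2 is given above. The members with the smallest p were higher, CCND2, a cyclin of the G1 phase, from 1382 ± 86 to 3394 ± 422 (1.29 ± 0.10), and PCNA, the clamp of DNA polymerase, from 474 ± 22 to 851 ± 31 (0.84 ± 0.09). Untreated pool 1 stood apart, with a mean log2 level of this list of 6.95 against 6.20 and 6.36 in the other untreated pools. The fall had adjusted p = 0.0219 by camera, adjusted p = 0.717 with an estimated correlation, and adjusted p = 0.1 without untreated pool 1 (0.000301 to 0.717 over its alternatives), where 16 members were lower and 7 higher and the median was -0.68.

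Antioxidant, p53 target and growth factor genes showed changes in both directions and no shift by camera. Of 31 antioxidant genes 7 were higher and 11 lower, with a median of -0.15 but a mean of 0.29 and, with library totals, a median of 0.07 (camera adjusted p = 0.635). GCLC, the rate-limiting enzyme of glutathione synthesis, rose from 557 ± 47 to 1067 ± 12 (0.94 ± 0.10). Without untreated pool 2, untreated pool 3, hypoxia pool 2 or hypoxia pool 3 the lower members of that list were 7, 5, 6 and 6, and 3 with library totals. Of 24 p53 target and apoptosis genes 7 were higher and 5 lower (adjusted p = 0.834), with TP53INP1 up from 347 ± 26 to 1227 ± 211 (1.81 ± 0.13). The lower ones were 3 without untreated pool 1, untreated pool 3 or hypoxia pool 2, and 2 with library totals. Of 48 growth factor signalling genes of the lens 21 were higher and 14 lower, or 22 and 8 with library totals (adjusted p = 0.824). FGFR4 rose from 517 ± 6 to 2015 ± 423 (1.94 ± 0.13) and PDGFRA fell from 729 ± 140 to 244 ± 30 (-1.57 ± 0.15). The counts of these lists were the same adjusted over the list alone.

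Camera called no list of markers of other cell types, while fry called the 3 leukocyte markers higher (adjusted p = 0.0292, 0.0292 to 0.956 over its alternatives), with adjusted p = 0.888 by camera with an estimated correlation. Of these 3, 1 was called higher, and their median log2 fold change was -0.37, opposite to the direction of fry. Of 20 lens epithelium markers, the layer removed by dissection, 4 were higher and 9 lower (also adjusted over the list alone), and 7 and 2 with library totals, under which the median turned from -0.21 to 0.004 (adjusted p = 0.363). PDGFRA, which is also in the growth factor list, was among the lower ones and the Wnt receptor gene FZD6 rose from 587 ± 99 to 1184 ± 86. Of 4 erythrocyte markers CA2, a carbonic anhydrase, rose from 7330 ± 1065 to 30066 ± 7586 (2.02 ± 0.18) and ANK1 fell by 1.64 ± 0.27 on the log2 scale (adjusted p = 0.870 for the list). Of 3 leukocyte markers IRF8 rose from 75.7 ± 9.7 to 299 ± 64 and CD74 was at 114 ± 37 and 85.0 ± 19.5 (-0.40 ± 0.26, adjusted p = 0.213), with adjusted p = 0.834 for the list. Of 4 endothelial and mesenchymal markers PECAM1 fell by 2.10 ± 0.33 and COL3A1 rose by 1.14 ± 0.19 on the log2 scale (adjusted p = 0.882 for the list, with 2 higher and 1 lower). Of 11 retina and pigment markers 3 were higher, among them MITF (1.25 ± 0.16), and 4 lower, among them OPTC (-1.77 ± 0.22) and COL9A1 (adjusted p = 0.363).

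**Figure D3:**
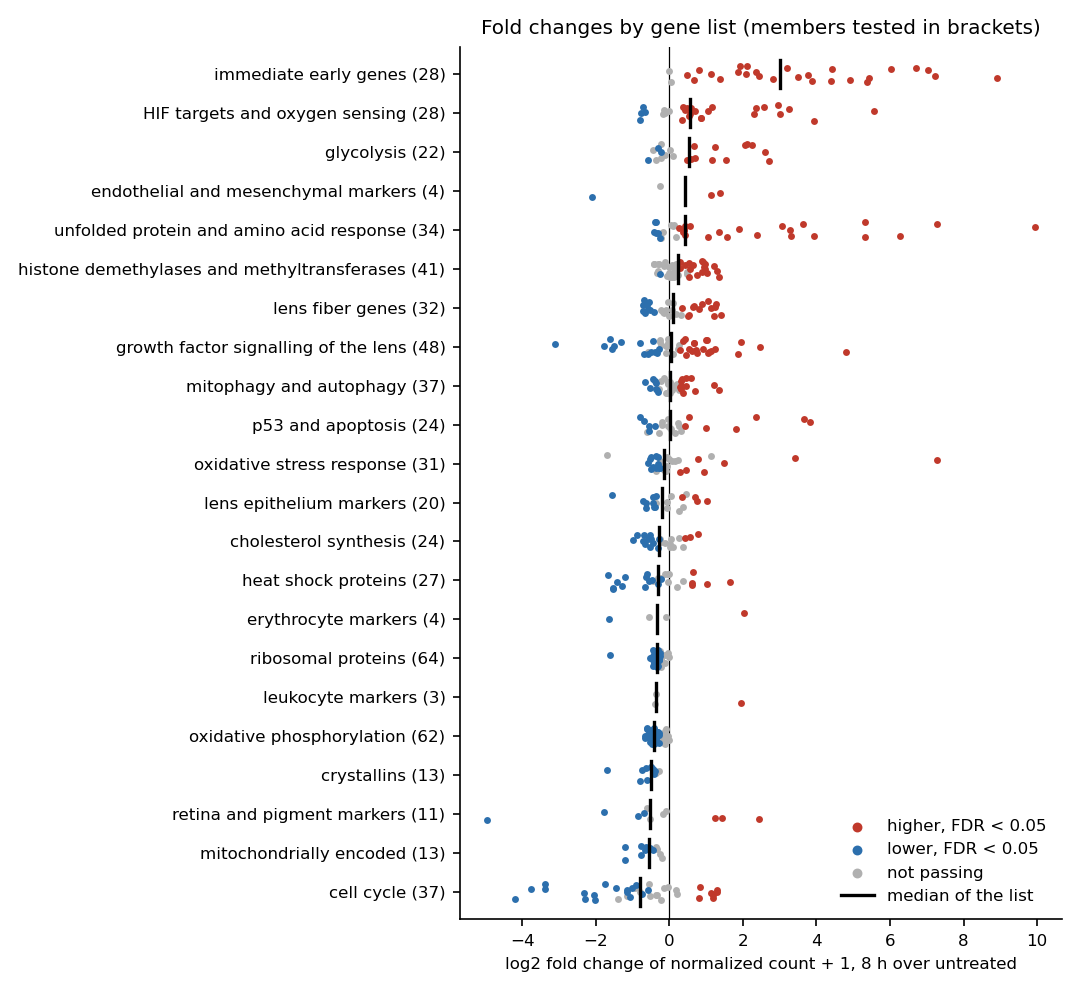
Log2 fold change of 8 h in 1% O2 over untreated (horizontal) for each measured member of the 22 gene lists, 1 point per gene, red for called higher, blue for called lower and grey for not passing, with the list's median as a black bar and the number of members tested in brackets. Medians run from 3.01 for immediate early genes to -0.81 for cell cycle genes, and with library totals those of the lens epithelium and oxidative stress lists turn to 0.004 and 0.07.

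The authors' deposited table gives its own comparison of the same libraries, with 2556 genes higher and 2042 lower at an adjusted p under 0.05 among the genes kept. Of these, 2532 and 2020 were called in the same direction here and 0 in the opposite one. The fit here called 465 genes that the authors did not, and 46 genes were called by the authors only. Fold changes had the same sign in 99.2% of genes, with Pearson's r of 0.988 and Spearman's rho of 0.999 across 9105 genes. The authors' log2 fold changes are shrunken and those here are not, so some of the largest differ in size. HBEGF had 2.59 from the authors against 9.0 here, R3HDML -3.16 against -5.39 and COL9A1 -2.23 against -4.95. Others were close, such as NRIP3 with -4.36 against -4.59. Both rest on the same libraries, and genes are not independent replicates.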

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

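Directions and calls held in most alternatives: 0 genes were called in the opposite direction under any setting, and leaving out each library in turn gave 2345 to 2565 genes higher and 1716 to 2249 lower. Counts fell with a test against a 1.5-fold change (883 higher, 205 lower), with a fold change of at least 2 (926 and 361) and, among lower genes, with an adjusted p under 0.01 (1395) and library totals (976), the first 3 by their stricter rule. With an estimated correlation 0 of the 22 lists were called (lowest adjusted p = 0.327, for HIF targets), against 12 with the preset one and 16 by fry, with adjusted p = 0.717 for glycolysis, 0.661 for crystallins and 0.661 for histone enzymes. Without 1 library the adjusted p ran from 0.0118 to 0.0628 for glycolysis and from 0.00706 to 0.0749 for histone enzymes. By fry the adjusted p was 0.019 for lens fiber genes, 0.0464 for p53 target genes, 0.0464 for growth factor genes and 0.0292 for leukocyte markers, which camera did not call, 0.091 for cell cycle genes, which camera did, and in the opposite direction to camera 0.0464 for oxidative stress genes and 0.304 for erythrocyte markers. Also reversed in direction, all without passing, were erythrocyte markers (adjusted p 0.717 to 0.961 without 1 library), endothelial markers (0.871 with library totals, 0.795 to 0.961 without 1 library), YBX1 (log2 fold change 0.002 with library totals) and BNIP3L (-0.005 with recomputed median-ratio factors, -0.022 to 0.048 without 1 library). The causes of these changes were not tested. With the replicate block there were 2786 genes higher and 2527 lower, with 6 glycolysis genes lower instead of 3, 7 lens epithelium markers higher instead of 4 and 10 lower instead of 9, and ASL1 called lower (adjusted p = 0.0178). As a hint from the data and not the design, same-number pools correlated at 0.117, 0.108 and 0.013, and untreated pool 3 correlated best with hypoxia pool 1 (0.026) and hypoxia pool 3 with untreated pool 2 (0.059), so whether the numbers pair the samples stays open. With crystallins left out of the scaling there is no value for that list, and the count model foreseen for counts was not run. Depth limits the lowest genes, where 1 read is a normalized count of 0.789 to 1.343.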

Other observations

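Some genes outside the naming rule stood out, and all genes of this paragraph were chosen after their values were seen. In the list of the unfolded protein and amino acid response, DDIT3 rose from 58.3 ± 18.8 to 2356 ± 552 (log2 fold change 5.33 ± 0.23), ASNS, which makes asparagine, from 635 ± 59 to 6282 ± 63 (3.31 ± 0.09), and their regulator ATF4 from 3026 ± 198 to 9018 ± 494 (1.58 ± 0.09). BMP4 rose from 6.0 ± 5.0 to 155 ± 29 (4.80 ± 0.58), ID3, a target of BMP signalling, from 445 ± 114 to 1598 ± 278 (1.86 ± 0.19), and TGFBR2 by 2.47 ± 0.39 on the log2 scale. Among lens fiber genes the transcription factor genes MAF and PROX1 rose by 0.80 ± 0.10 and 0.65 ± 0.16, while the water channel gene MIP and the beaded filament gene BFSP2 fell by 0.52 ± 0.14 and 0.57 ± 0.12.

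Of the tests that follow, the scaling tests of both families and the one of time in culture were chosen only after the result was seen. Splitting the 6 libraries into 3 and 3 in all 10 ways gave 5017 genes for the real split and at most 0 for any other, so 1 split of 10 reached the real count, and with 10 splits that share cannot go under 0.1. Every other split puts pools of both groups on each side, so differences between the groups widen the spread within a side. Counts of 0 there were therefore likely beforehand, and no conclusion is drawn from them.

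Ribosomal protein and respiratory chain genes were lower as families (adjusted p = 0.717 and 0.661 with an estimated correlation), which the scaling or a trend of fold change with expression level could produce. With library totals the mean log2 level of respiratory chain genes differed by -0.167, against -0.384 with the deposited scaling. That is still more than the summed SDs of the groups (0.123), so library totals did not remove the fall. The margin was small, with hypoxia pool 1 at 10.33 and the lowest untreated pool at 10.363. A comparison with library totals alone cannot exclude scaling as a cause. For ribosomal proteins the difference was -0.125 against summed SDs of 0.241, and the test cannot tell. Among 10000 lists matched on mean level the medians stood at percentile 0.04 for ribosomal proteins and 0.01 for respiratory chain genes, the latter the smallest that 10000 lists can give, so a level trend alone does not reach the fall of either, although lists drawn gene by gene leave the correlation within a family out of account. For ribosomal proteins the matched lists had a median of -0.214 against -0.341, so genes of that level were lower too, and for respiratory chain genes -0.031 against -0.407.

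Untreated pool 1 held 141 genes at least 2 times above the other untreated pools on the log2(value + 1) scale. By the same measure untreated pools 2 and 3 held 30 and 18, and hypoxia pools 1 to 3 held 28, 47 and 76. Among the 141 of untreated pool 1 were 3 of the 6 largest falls and 9 cell cycle genes, but also the large rises CHAC1, HBEGF and EGR2. Some rest on very few reads, such as EGR2 at 1, 0 and 0 in the untreated pools. Uneven carry-over of another tissue part could make genes in excess in that pool look lower at 8 h. Without that pool the median log2 fold change of the 141 genes was -0.019, with 44 lower and 43 higher. Matched lists had a median of -0.128, and -0.019 lies inside their central 95% (-0.271 to 0.037), so the test cannot tell. Cell cycle genes as a list were in excess in that pool by 0.529 on the log2 scale (the central 95% of matched lists ran from -0.057 to 0.218), and without it their median was -0.682 (percentile 0.01). Camera without that pool did not call their fall (adjusted p = 0.1), and the matched lists leave the correlation between genes out of account. Lens epithelium as that part is also left open: its list was in excess in that pool by 0.129 on the log2 scale (the central 95% of matched lists ran from -0.123 to 0.025), but its median without the pool was -0.095 (percentile 66.4), and 0 of its genes were among the 141.

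HIF target, immediate early and unfolded protein response genes were mostly higher at 8 h. By camera with an estimated correlation their adjusted p was 0.327, 0.382 and 0.661. Not all stress genes rose: of 27 heat shock genes 13 were lower and 5 higher, and camera called no shift of antioxidant genes. Low oxygen, time in culture or dissection could cause the rises. The RNA-seq libraries held 8 h in normal oxygen analysed here number 0, so the test cannot tell. Libraries of lenses cultured 8 h in normal oxygen would separate low oxygen from time in culture and dissection, but not those from each other.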
